A study of Drosophila melanogaster with 25 samples.

How the data were processed

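The study measured RNA of Drosophila melanogaster brains in 25 libraries, which the labels place in 4 groups by sex and treatment (control or photodynamic exposure, PDE). The titles of the treated samples say PDT where the design text of the series says PDE, and both were read as the same treatment. Per the labels' protocols, RNA was extracted with a Maxwell RSC simplyRNA kit and libraries were made with the SMART-Seq mRNA LP kit of Takara. The submitters' processing notes name the aligner STAR and the genome build dm6, both without a version. The read counter, its strand setting, its treatment of reads shared between genes and the gene annotation are not given in the sources used here. Groups and replicate numbers were taken from the labels, and each column of the table was assigned by its name. There were 0 columns of values that could not be assigned.

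The authors deposited 1 table of RPKM values, reads per kilobase of gene length scaled to the total reads of the library, with 16060 genes under FlyBase identifiers. Of these, 13581 were above 0 in at least 1 library. Symbols and positions came from the Ensembl BDGP6.54 annotation (release 115), which names 15996 of the identifiers and not the other 64. Genes that are not in the table were not analysed here.

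Because a gene's RPKM values are whole multiples of what 1 read is worth, reads and library totals were recovered from the steps between low values. Reads were recovered for 13578 genes, and 100% of their values above 0 came out whole within a tolerance of 0.001. With the annotated genomic span alone as the length, 90.8% of the values of few reads were whole, against 0.2% by chance. The recovered reads summed to 99.83 to 99.94% of each library total. Among 9248 genes with introns the length in use equalled the genomic span, introns included, in 87.3% and the summed exon length in 0%, with a median ratio to the exon length of 1.276. The deposited RPKM of a gene with long introns is therefore lower than RPKM computed over exons would be, and a minimum RPKM removes such genes more readily. Of 8594 genes with at least 1 read per 1e6 in at least 5 libraries, 799 were left out by the minimum of 1 RPKM, with a median length of 7106 bases against 2766 for the genes kept. The ratio of a gene's RPKM between 2 libraries does not depend on its length, but on the log2(RPKM + 1) scale a longer length brings a gene nearer to the pseudocount and shrinks its change. With log2 of recovered reads per 1e6, which holds no length, and the 8594 genes past the minimum of 1 read per 1e6, 435 and 473 genes differed between the sexes in controls and after PDE, against 379 and 393, where both the scale and the genes tested had changed.

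Values were analysed as log2(RPKM + 1), scaled as deposited, for the 7985 genes with at least 1 RPKM in at least 5 libraries. A linear model with 1 coefficient per group was fitted to all 25 libraries with limma 3.58.1 in R 4.3.3, with moderated errors and an intensity trend. The contrasts were PDE against control in females, in males and averaged over the sexes, the male minus the female change, and males against females in controls and after PDE. Genes with an adjusted p (Benjamini-Hochberg, over all genes of a contrast) under 0.05 were called. Standard errors are those of limma's moderated fit and standard deviations are of RPKM within a group.

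Of 39 gene lists fixed before the data were examined, those with at least 3 measured genes, except the sex markers (11 measured) and the 13 genes named in any case, were tested with limma's camera, which ranks a list against all other genes, with a preset correlation between genes of 0.01. The test was repeated with a correlation estimated from the residuals of each list. Members were also counted with p-values adjusted over the list alone.

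The genes named in the text were chosen by a rule. For females and males these were the called genes with a group mean of at least 5 RPKM in the higher group, up to 10 with the largest rise and 10 with the largest fall, and for the average up to 10 further ones per direction with the smallest p. For the difference of the changes these were the 5 smallest p-values per direction, for the sexes in controls the 8 largest differences per direction and the genes of sex determination, and for each list up to 4 members with the smallest p. A fixed set of 13 measured genes known from oxidative stress, light sensing and metabolism was named in any case. Genes outside the rule are said to have been chosen after their values were seen.

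Library measures were compared between PDE and control within each sex by exact two-sided permutation of the labels. The correlation of the female and male changes was set beside 99 permutations of the treatment labels within each sex. Correlations within groups used values centred on their group mean and 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

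The fit was tested on simulated data with 200 changed genes. In the female comparison (7785 genes) 89, 95, 100 and 98% of genes changed by 1.5, 2, 4 and 8 times were called, and in the male comparison (7803 genes) 83, 91, 96 and 100%, with 10 false calls in each. These shares hold for the simulated values with 200 changed genes and are not the power for the real genes. In the real female comparison TotA, at means of 29.8 and 471 RPKM in control and PDE libraries, did not pass (limma adjusted p = 0.061). Recovered counts of libraries of the same group were compared to find libraries deposited more than 1 time. The smallest chi-square per degree of freedom was 11.8, far above sampling noise, so each library was counted as 1 sample.

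The alternatives were other pseudocounts (0.1 and 5), no minimum and a minimum of 5 RPKM, median-ratio scaling, quantile normalization, a fit of only the groups compared, array weights, robust moderation, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were log2 of recovered reads per 1e6, limma voom on recovered reads, the mean of the retina list alone or with that of the fat body list as covariates, and fits without the 2 libraries under 15 M reads or without the 5 libraries with at least 100 RPKM of trp.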

Results

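Brain RNA of Drosophila melanogaster was sequenced in 25 libraries from 4 groups: female controls (n = 5), females after long-term photodynamic exposure (PDE, n = 7), male controls (n = 7) and males after PDE (n = 6). A photodynamic exposure pairs light with a photosensitising compound so that reactive oxygen species form in the tissue. The series asks how a long exposure of this kind changes the response to oxidative stress. The compound, the light and the duration are not given in the sources used here. The values are RPKM, reads per kilobase of gene length scaled to the library's total reads. Library totals recovered from those values ran from 8.88 M to 26.1 M reads in female controls (median 23.42 M) and from 21.58 M to 48.3 M after female PDE (median 26.16 M). They ran from 27.83 M to 58.73 M in male controls (median 31.71 M) and from 11.2 M to 28.26 M after male PDE (median 26.55 M). The labels do not say whether libraries of a group came from separate flies or pools, so each p-value measures the spread between these samples, which may be partly technical. The tests, the gene lists and the rule for named genes were fixed before the data were examined, and later choices are named as such. The noncoding RNAs roX1 and roX2 of the male dosage compensation machinery were at 1870 to 2160 and 143 to 261 RPKM in male controls. Female controls held 9.58 to 36.8 and 0.703 to 2.88 RPKM, and every library matched its labelled sex.

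The female comparison asks which brain transcripts differed after PDE. Arc1 and Arc2, neighbouring genes for capsid-forming proteins derived from a retrotransposon Gag, rose from 24.5 ± 4.19 to 75.0 ± 15.2 RPKM and from 3.13 ± 1.22 to 7.31 ± 1.57 RPKM (SD, n = 5 and 7). Xrp1, a stress-inducible bZIP transcription factor, rose from 18.7 ± 2.22 to 31.1 ± 1.61 RPKM. CG14695 rose from 2.97 ± 0.537 to 5.79 ± 1.26 RPKM and CG3008 from 11.9 ± 1.45 to 15.3 ± 0.758 RPKM. CG9377 fell from 14.2 ± 3.62 to 5.24 ± 1.55 RPKM. For each of these 6 genes all 7 PDE libraries lay beyond every female control, a separation that 25 of the 7985 genes tested showed (0.31%, against 0.25% by chance).

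Changes are given on the log2(RPKM + 1) scale, on which those of low genes are understated. limma with Benjamini-Hochberg adjustment gave Xrp1 a change of 0.71 (SE 0.076, adjusted p = 1.98e-05), CG9377 −1.29 (SE 0.164, adjusted p = 0.000174) and Arc1 1.57 (SE 0.231, adjusted p = 0.00145). The changes of CG14695 and Arc2 were 0.76 (SE 0.116, adjusted p = 0.0019) and 1.05 (SE 0.174, adjusted p = 0.00557), and that of CG3008 was 0.35 (SE 0.067, adjusted p = 0.0395). No other gene passed: 5 rose and 1 fell. An unadjusted p under 0.05 was found for 383 genes, no more than chance gives on average over the 7985 genes tested. The Turandot gene TotA, which encodes a secreted stress protein, was at 29.8 ± 29.2 RPKM in controls and 471 ± 466.4 RPKM after PDE without passing (log2 change 3.75, SE 0.762, adjusted p = 0.061). All 7 PDE libraries lay above its control median. TotC changed by 3.255 (SE 0.747, limma adjusted p = 0.156) and TotM by 2.91 (SE 0.786, limma adjusted p = 0.355). Of the 7 PDE libraries 6 lay above the control median for TotC and 7 for TotM. Arc1 and Arc2 are related in sequence, as are the Turandot genes, so reads of one copy can have been counted for another. With only the female groups in the fit 3 genes passed, and Arc2 and CG14695 did not (limma adjusted p = 0.17 and 0.107). CG3008 lost its call with 15 of the 25 libraries left out in turn (limma adjusted p up to 0.115).

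In the dm6 assembly, with positions from the Ensembl BDGP6.54 annotation, Xrp1 (FBgn0261113) spans 18914968 to 18926989 on chromosome arm 3R. Arc1 (FBgn0033926) and Arc2 (FBgn0033928) lie beside each other on 2R at 14357927 to 14360297 and 14361924 to 14362825. CG14695 (FBgn0037850) lies on 3R at 10878204 to 10879319, CG9377 (FBgn0032507) on 2L at 13359901 to 13361565 and CG3008 (FBgn0031643) on 2L at 4883298 to 4885669. TotA (FBgn0028396) and TotC (FBgn0044812) are neighbours on 3R at 20871036 to 20871700 and 20872988 to 20873580. TotM (FBgn0031701) lies on 2L at 5329857 to 5330464, Gadd45 (FBgn0033153) on 2R at 7249161 to 7250655 and GstE1 (FBgn0034335) on 2R at 18398393 to 18399223. Sting (FBgn0033453) lies on 2R at 9842686 to 9845512, CG17224 (FBgn0031489) on 2L at 3016441 to 3018308 and the noncoding lncRNA:CR32368 (FBgn0052368) on 3L at 7915437 to 7915846. Apart from lncRNA:CR32368 these are protein-coding genes, and each value covers the whole gene.

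**Figure D1:**
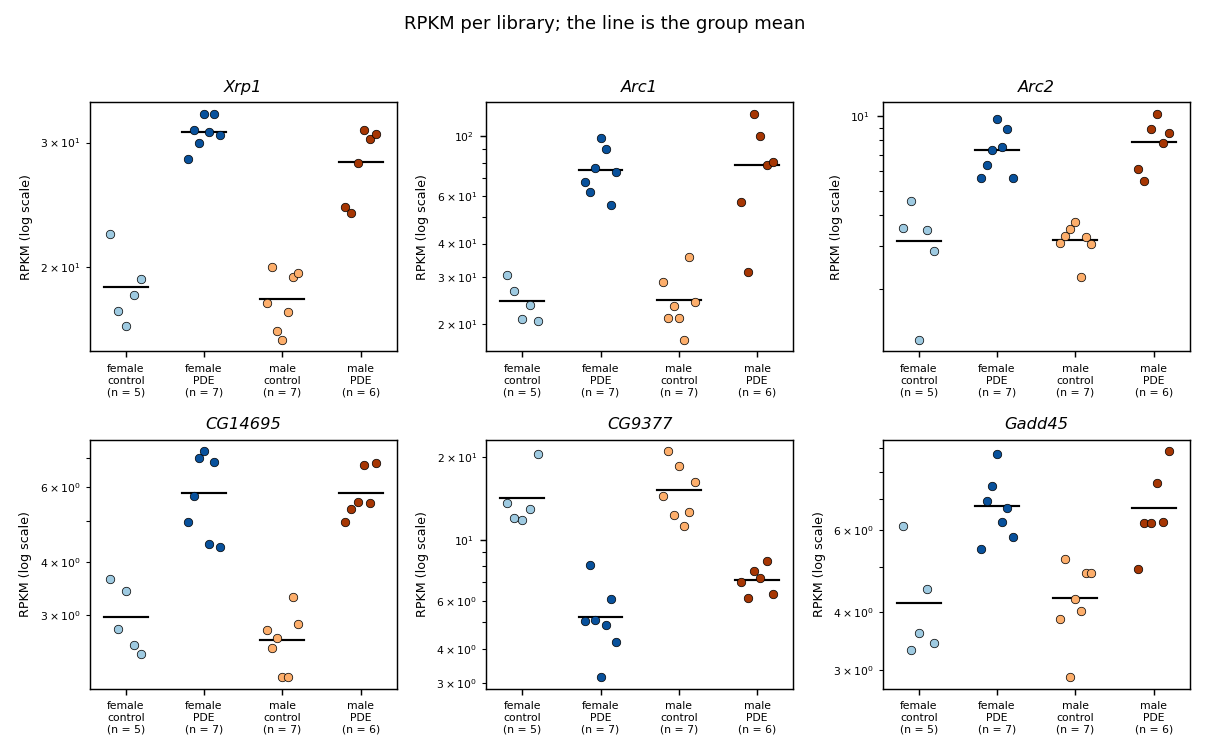
RPKM on a log scale (vertical axis) for Xrp1, Arc1, Arc2, CG14695, CG9377 and Gadd45 in each library of the 4 groups (horizontal axis), where points are libraries and the line is the group mean. After female PDE Xrp1 lies between 28.4 and 32.9 RPKM, above every female control (16.5 to 22.3 RPKM).

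The male comparison asks the same question in males. The Turandot genes had the largest rises among the genes that passed, TotC from 0.548 ± 0.317 to 64.9 ± 66.3 RPKM, TotA from 12.4 ± 6.01 to 449 ± 441 RPKM and TotM from 0.50 ± 0.364 to 51.8 ± 77.1 RPKM (SD, n = 7 and 6). In all 6 PDE libraries each of them was above every male control. Male PDE 6 raised these means most, at 192, 1302 and 207 RPKM for TotC, TotA and TotM. The next highest male PDE library was at 74.3, 522 and 34.6 RPKM. Arc1 rose from 24.6 ± 6.01 to 78.1 ± 31.7 RPKM, Arc2 from 3.17 ± 0.477 to 7.85 ± 1.78 RPKM and Xrp1 from 18.02 ± 1.68 to 28.1 ± 3.31 RPKM. CG14695 rose from 2.63 ± 0.412 to 5.81 ± 0.785 RPKM and CG7084 from 36.7 ± 5.04 to 49.0 ± 4.02 RPKM. CG9377 fell from 15.2 ± 3.61 to 7.14 ± 0.830 RPKM and lncRNA:CR32368 from 107 ± 111 to 9.83 ± 2.51 RPKM. CG4887 and su(w[a]), a regulator of splicing, fell by less, from 106 ± 7.55 to 88.6 ± 5.03 RPKM and from 21.3 ± 0.976 to 18.3 ± 0.772 RPKM.

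limma with Benjamini-Hochberg adjustment gave log2 changes of 4.89 for TotC (SE 0.71, adjusted p = 0.000864), 4.71 for TotA (SE 0.724, adjusted p = 0.00154) and 4.11 for TotM (SE 0.747, adjusted p = 0.0125). Xrp1 changed by 0.61 (SE 0.072, adjusted p = 8.91e-05), CG14695 by 0.91 (SE 0.111, adjusted p = 8.91e-05) and Arc1 by 1.54 (SE 0.219, adjusted p = 0.000823). Arc2 changed by 1.07 (SE 0.165, adjusted p = 0.00154), CG7084 by 0.41 (SE 0.084, adjusted p = 0.0395), CG9377 by −0.97 (SE 0.155, adjusted p = 0.00223) and lncRNA:CR32368 by −2.77 (SE 0.557, adjusted p = 0.0375). CG4887 changed by −0.25 (SE 0.05, adjusted p = 0.0286) and su(w[a]) by −0.21 (SE 0.043, adjusted p = 0.04), with all 6 PDE libraries below every control in both. Altogether 14 genes passed, 9 higher and 5 lower, where 319 had an unadjusted p under 0.05, fewer than chance gives on average. The remaining ones, under a mean of 5 RPKM and named after their values were seen, were Sarm, an NAD-cleaving enzyme of axon degeneration (0.22, SE 0.045, adjusted p = 0.04), and CG17264 (−1.18, SE 0.244, adjusted p = 0.04). In 11 of the 14 the groups did not overlap, which 29 genes showed (0.36%, against 0.12% by chance). Without the 5 libraries richest in retinal transcripts, an alternative chosen after seeing the data, 6 genes passed, and Arc2 and TotM did not (limma adjusted p = 0.112 and 0.276). With limma voom on recovered reads, also chosen after seeing the data, TotC and TotM did not pass (adjusted p = 0.606 and 0.657, range over the alternatives 0.000115 to 0.606 and 0.00238 to 0.657), nor did TotM with pseudocount 5 (limma adjusted p = 0.107). With array weights 25 genes passed, quantile normalization gave 11 higher and 2 lower, 8 genes passed without male control 2 or 5 or male PDE 3, 4 or 5, and 9 without male control 1, 3 or 4 or male PDE 1 or 6. With 1 of the 25 libraries left out in turn su(w[a]) lost its call 18 times, CG7084 13, lncRNA:CR32368 10 and CG4887 8 (limma adjusted p up to 0.179, 0.141, 0.108 and 0.0983).

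**Figure D2:**
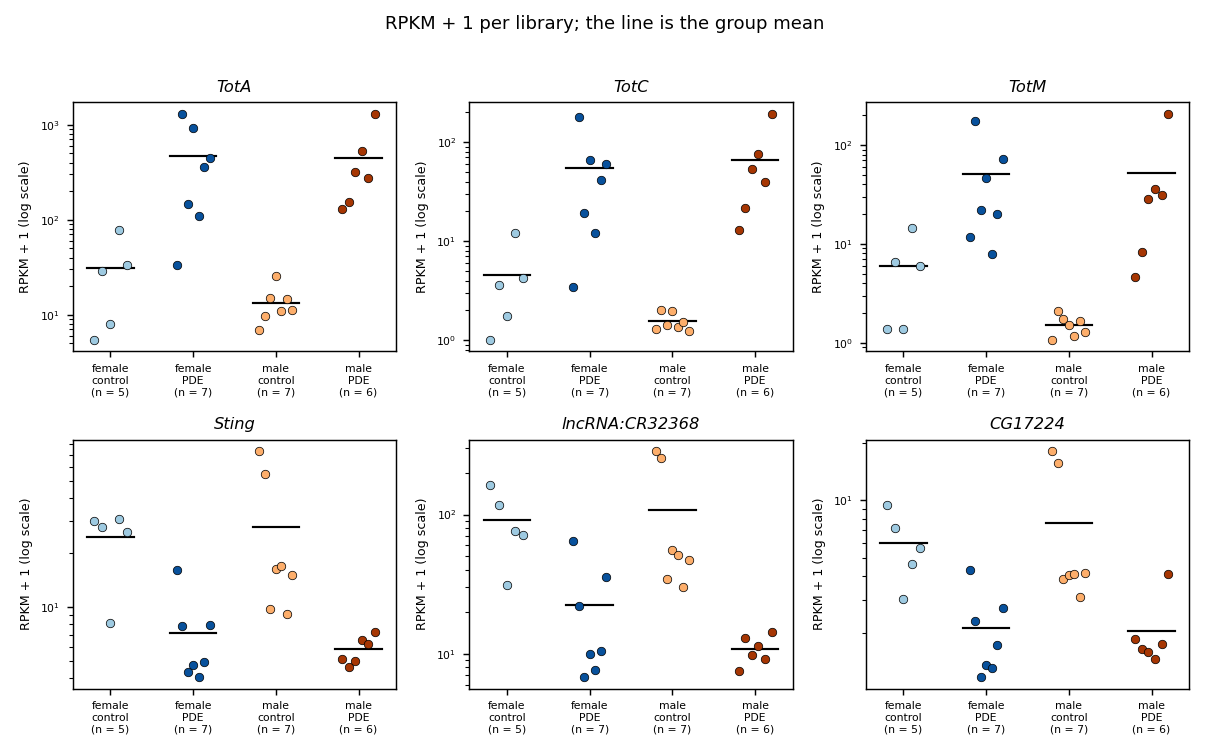
RPKM + 1 on a log scale (vertical axis) for TotA, TotC, TotM, Sting, lncRNA:CR32368 and CG17224 in each library of the 4 groups (horizontal axis), where points are libraries and the line is the group mean. TotA spans 127 to 1300 RPKM after male PDE against 5.94 to 24.5 RPKM in male controls, and Sting reaches 72.5 RPKM in male controls against at most 6.25 RPKM after male PDE.

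Averaged over the sexes, 33 genes passed limma with Benjamini-Hochberg adjustment, 26 higher and 7 lower, all in the same direction in females and males. The test of the mean of both changes favours such genes, so this agreement is no separate result. An unadjusted p under 0.05 was found for 512 genes. Gadd45, a stress sensor induced by DNA damage, rose from 4.19 ± 1.17 to 6.76 ± 1.10 RPKM in females and from 4.28 ± 0.777 to 6.67 ± 1.36 RPKM in males (log2 change 0.57, SE 0.093, adjusted p = 0.00185). GstE1, a glutathione S-transferase, rose from 119 ± 24.1 to 184 ± 29.5 RPKM and from 130 ± 15.5 to 202 ± 50.1 RPKM (0.62, SE 0.103, adjusted p = 0.00205). Both were above the control median in 7 of 7 female and 6 of 6 male PDE libraries. Sting, an adaptor of cyclic dinucleotide signalling in antiviral defence, fell from 23.5 ± 9.35 to 6.10 ± 4.21 RPKM and from 26.9 ± 25.5 to 4.80 ± 1.03 RPKM (−1.82, SE 0.314, adjusted p = 0.00244). It was below the control median in 7 of 7 and 6 of 6 PDE libraries.

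The other rises named by the rule were CG12868 (log2 change 0.59, SE 0.098), the UDP-glycosyltransferase Ugt301D1 (0.49, SE 0.1), CG42365 (0.34, SE 0.073) and Ku80 of the end-joining repair of DNA breaks (0.30, SE 0.065). CHKov1 (0.28, SE 0.064), the metalloprotease Invadolysin (0.22, SE 0.039) and the O-GlcNAc transferase sxc (0.11, SE 0.025) rose by less, and the limma adjusted p of these 7 genes ran from 0.00205 to 0.0464. CG17224 fell by 1.56 on the log2 scale (SE 0.293, adjusted p = 0.00716 by limma) and Arglu1 by 0.16 (SE 0.034, adjusted p = 0.0313). Among genes under a mean of 5 RPKM, named after their values were seen, the glutathione S-transferase GstD5 rose by 0.73 (SE 0.153), CG8501 by 0.60 (SE 0.135), the cytochrome P450 Cyp12c1 by 0.52 (SE 0.117) and the telomere protein gene ver by 0.45 (SE 0.077). LManI rose by 0.42 (SE 0.093), RnrL, the large subunit of ribonucleotide reductase, by 0.29 (SE 0.064) and CG14615 by 0.28 (SE 0.048). On the opposite strand, su(w[a]) shares 12720 bases with CG11638, Arglu1 903 with an antisense RNA, Invadolysin 728 with CG34303, GstE1 127 with GstE10, Sting 55 with Orc6 and CG14695 54 with Sodh2, and the strand setting of the counting is not given, so these values can hold reads of both. Ku80, sxc, CHKov1, CG42365 and Arglu1 each lost their calls with 10 or more of the 25 libraries left out in turn (limma adjusted p up to 0.0887, 0.0927, 0.104, 0.0789 and 0.0812), and Ugt301D1 without female control 3 or male PDE 4 (up to 0.0577).

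The 13 genes chosen beforehand from oxidative stress, light sensing and metabolism did not pass over all genes in females, in males or in the average. Superoxide dismutase 1 (Sod1) was at 196 ± 41.4 and 203 ± 24.9 RPKM in female control and PDE libraries and at 208 ± 17.4 and 219 ± 22.2 RPKM in males, with an averaged log2 change of 0.07 (SE 0.074). The averaged changes were 0.04 for Sod2 (SE 0.081), 0.10 for catalase, Cat (SE 0.075), 0.07 for GstD1 (SE 0.113), 0.07 for the thioredoxin reductase Trxr1 (SE 0.046) and −0.02 for Gclc (SE 0.039). For cnc, the fly Nrf2, and its partner Keap1 they were 0.04 (SE 0.038) and 0.02 (SE 0.042). They were 0.10 for ref(2)P (SE 0.054), −0.01 for Thor (SE 0.273), 0.07 for the cryptochrome cry (SE 0.09) and −0.70 for the rhodopsin ninaE (SE 1.03). In females the 13 changes lay between −0.05 for ninaE and 0.14 for Sod2, and in males all but that of Hsp68 between −1.34 for ninaE and 0.13 for ref(2)P. Hsp68 had the smallest p, at 2.08 ± 0.514 and 2.96 ± 0.597 RPKM in male control and PDE libraries (log2 change 0.37, SE 0.106, adjusted p = 0.411 by limma), and adjusted over the list alone it passed in males (adjusted p = 0.0261). Its averaged change was 0.22 (SE 0.077, adjusted p = 0.425 by limma). The female changes of Sod1, Sod2, GstD1, Trxr1, Hsp68, Thor, cry and ninaE changed sign under at least 1 alternative, as did the male changes of Sod2, Gclc, Thor and cry.

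The 23 measured antioxidant enzymes of the list did not rank apart from other genes in the average (camera of limma, adjusted p = 0.664, median log2 change 0.04). Of them 0 passed over all genes tested and 0 adjusted over the list alone, with an unadjusted p under 0.05 in 0. Among 29 glutathione S-transferases GstE1 and GstD5 rose over all genes tested, and adjusted over the list alone GstT1 did too (0.16, SE 0.042). That list ranked higher under PDE in the average and in males (camera adjusted p = 0.0102 and 0.034; adjusted p = 0.8 and 0.868 with an estimated correlation). The 30 cytochrome P450s ranked higher in females, in males and in the average (camera adjusted p = 0.00585, 0.00255 and 7.05e-05; adjusted p = 0.985, 0.868 and 0.759 with an estimated correlation). Of these 25 had a positive averaged change, and Cyp12c1 was the 1 that passed over all genes tested and adjusted over the list alone. Next came Cyp4g15 (0.30, SE 0.098), Cyp6a13 (0.17, SE 0.06) and Cyp12e1 (0.19, SE 0.071). With no filter on low values the P450 list passed in none of the 3 (camera adjusted p = 0.392, 0.226 and 0.152), and in females it did not without female control 1, female PDE 4 or female PDE 5 (up to 0.422) or with array weights (0.277). The glutathione S-transferases did not pass in males without female control 3, male control 1, 2 or 3 or male PDE 3 or 5 (camera adjusted p up to 0.378), nor in the average without female control 1 or male PDE 3 (up to 0.654) or with array weights (0.156).

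Of 17 genes of the JNK and p53 damage response, Xrp1 and Gadd45 rose over all genes tested, and adjusted over the list alone the matrix metalloprotease Mmp1 rose too (0.38, SE 0.109). The fly TNF gene egr was at 0.16 (SE 0.072). The list ranked higher with camera in females, in males and in the average (adjusted p = 0.000367, 0.00261 and 3.24e-05), with adjusted p = 0.156, 0.342 and 0.0793 with an estimated correlation. Of 9 JAK-STAT targets and Turandot genes TotA, TotC and TotM rose, and adjusted over the list alone Tep2 too (0.39, SE 0.124). This list ranked higher in females, in males and in the average (camera adjusted p = 0.000367, 1.51e-06 and 7.78e-07), with adjusted p = 0.156, 0.0438 and 0.0363 with an estimated correlation. Its mean log2 change was 1.35 and its median 0.07. In females 0 members passed over all genes tested and TotA, TotC and TotM adjusted over the list alone, and in the JNK and p53 list Xrp1 passed over all genes and Mmp1 and Gadd45 adjusted over the list alone. In males Tep2 and Gadd45 were added adjusted over the list alone. Among 24 genes of DNA repair and checkpoints Ku80 rose over all genes tested, and adjusted over the list alone Ku80, PCNA (0.29, SE 0.092) and Irbp, the partner of Ku80 (0.24, SE 0.076). The list did not rank apart (camera adjusted p = 0.664).

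The 24 measured antimicrobial peptide genes did not rank apart from other genes in the average (camera adjusted p = 0.708), with a median log2 change of 0.16 and a mean of −0.02. Members lay on both sides, such as Listericin (−0.58, SE 0.173), Dro (−1.61, SE 0.549), BomS2 (0.67, SE 0.311) and BomBc1 (0.37, SE 0.185), and none passed over all genes or over the list alone. Toll and IMD pathway components (adjusted p = 0.854), heat shock proteins and chaperones (0.223), the unfolded protein response (0.463), apoptosis (0.714) and autophagy and lysosome genes (0.708) did not rank apart with camera either. The nuclear-encoded respiratory chain did not in the average (camera adjusted p = 0.168) and ranked lower in males (camera adjusted p = 0.0304, median −0.02; adjusted p = 0.889 with an estimated correlation), which ended without male control 1 or 4 or male PDE 2, 5 or 6 (camera adjusted p up to 0.533). For the lists of cytosolic and mitochondrial ribosomal proteins, the TCA cycle, iron and heme handling, insulin signalling, eye pigment cells, the circadian clock, neurotransmitter synthesis, muscle, trachea and cuticle, and ovary and eggshell the camera adjusted p in the average lay between 0.0903 and 0.858. In the last of these Vm34Ca passed adjusted over the list alone (−1.13, SE 0.372). The direction given by camera, which is relative to all other genes, differed in sign from the median or mean change for antimicrobial peptides, Toll and IMD components, apoptosis, both kinds of ribosomal proteins, the TCA cycle, iron and heme handling, insulin signalling, muscle, trachea and cuticle, and ovary and eggshell.

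Haemocyte genes ranked higher in females, in males and in the average (camera adjusted p = 0.00954, 3.02e-05 and 1.5e-05; adjusted p = 0.985, 0.613 and 0.367 with an estimated correlation), with all 10 measured members positive in both sexes. Of these Col4a1 (0.32, SE 0.095), Ppn (0.55, SE 0.171) and NimC1 (0.74, SE 0.235) passed adjusted over the list alone and 0 over all genes tested. Glial genes ranked higher in females, in males and in the average (camera adjusted p = 0.000812, 0.022 and 7.96e-05; adjusted p = 0.551, 0.868 and 0.367 with an estimated correlation). In the average 14 of 17 were positive, with nrv2 at 0.17 (SE 0.063) and the glutamine synthetase Gs2 at 0.17 (SE 0.075), and none passed over all genes or over the list alone. Neuropeptide genes ranked lower in females and in the average (camera adjusted p = 4.37e-05 and 2.91e-05; adjusted p = 0.378 and 0.367 with an estimated correlation). Corazonin, Crz, was at −0.35 (SE 0.116) and CCHa1 at −0.12 (SE 0.062), and none of the 25 passed over all genes or over the list alone. Antennal and chemosensory genes ranked lower in females and in the average (camera adjusted p = 0.0131 and 0.00307; adjusted p = 0.156 and 0.0406 with an estimated correlation), with Or22a at −0.23 (SE 0.084) and Obp56d at −0.58 (SE 0.252). In females haemocyte genes did not pass without female control 1, female PDE 4 or female PDE 5 (camera adjusted p up to 0.691), with array weights (0.186) or with a minimum of 5 RPKM, and glial genes did not without female control 1 (0.157). In males glial genes did not pass without male control 3 or 5 or male PDE 4 or 5 (camera adjusted p up to 0.22). Antennal genes did not in females without female control 3 or female PDE 4 (camera adjusted p up to 0.534), nor in the average without female control 3 (0.0584), and in both not with array weights, limma voom or no filter on low values.

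Retinal and fat body transcripts differed strongly between libraries of the same group. ninaE ranged from 16.0 to 5300 RPKM in female controls, from 26.2 to 1160 after female PDE, from 45.5 to 5700 in male controls and from 11.9 to 5080 after male PDE. The retinal channel gene trp reached 100 RPKM or more in 5 libraries, female control 4, male controls 4, 5 and 6, and male PDE 3. The 28 phototransduction and retina genes ranked lower under PDE in females, in males and in the average (camera adjusted p = 0.0338, 0.00466 and 0.000579; adjusted p = 0.985, 0.868 and 0.8 with an estimated correlation). Without those 5 libraries the rank turned in all 3 (camera adjusted p = 0.565, 0.791 and 0.7), as it did in females without female control 4 alone (0.89). With other single libraries left out the call ended in females without female control 3 or female PDE 1, 4, 5 or 6, in males without male control 4 or 5 or male PDE 4 or 6 (camera adjusted p up to 0.425), and in the average without female control 3 or 4 (up to 0.141). The 10 fat body genes ranked lower in males and in the average (camera adjusted p = 0.0264 and 0.0348; adjusted p = 0.868 and 0.8 with an estimated correlation), with Yp1 at −1.16 (SE 0.483) and Lsp2 at −0.96 (SE 0.349). In the average proteasome (camera adjusted p = 0.00348), lipid metabolism (0.0118) and glycolysis genes (0.0475) ranked higher and pan-neuronal genes (0.0443) lower. With an estimated correlation these lists had adjusted p = 0.878, 0.768, 0.878 and 0.878. Proteasome genes ranked higher in males (camera adjusted p = 0.022; adjusted p = 0.868 with an estimated correlation) and glycolysis genes in females (camera adjusted p = 0.00313; adjusted p = 0.985 with an estimated correlation). In these lists no member passed over all genes tested, and nSyb of the pan-neuronal list passed adjusted over the list alone (−0.08, SE 0.023). Single libraries ended the calls of fat body genes (5 of the 25 left out in turn in males and 12 in the average, camera adjusted p up to 0.198 and 0.325), and in the average those of glycolysis (14, up to 0.573) and pan-neuronal genes (13, up to 0.447). Proteasome genes did not pass in males without male control 2, 5 or 7 or male PDE 3, 4 or 6 (camera adjusted p up to 0.243), nor in the average without female control 3 (0.357). Lipid metabolism did not in the average without female control 1, female PDE 4 or male PDE 6 (camera adjusted p up to 0.112), nor glycolysis in females without female control 1 or 3 (up to 0.403).

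**Figure D3:**
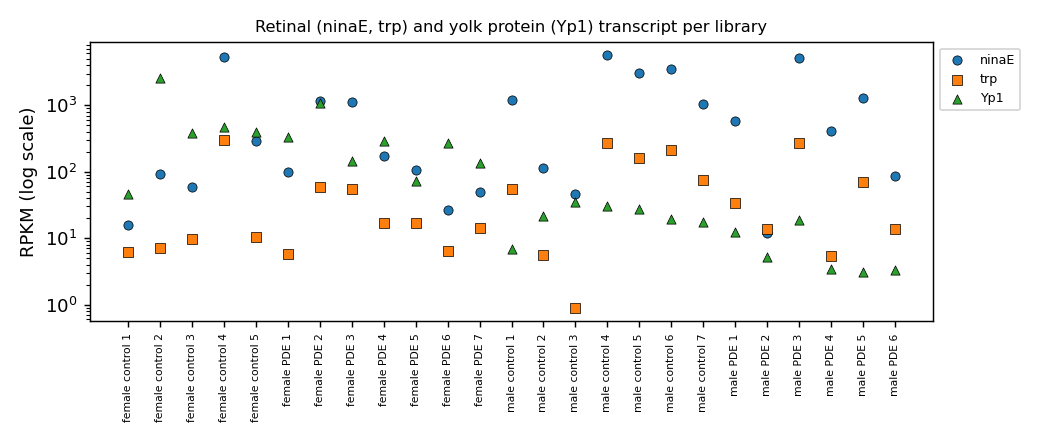
RPKM on a log scale (vertical axis) of the retinal genes ninaE and trp and the yolk protein gene Yp1 in each of the 25 libraries (horizontal axis), 1 symbol per gene. ninaE runs from 11.9 RPKM in male PDE 2 to 5700 RPKM in male control 4, and Yp1 from 3.14 RPKM in male PDE 5 to 2570 RPKM in female control 2.

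Whether PDE acted differently in the sexes was asked with the difference of the changes, male minus female. limma with Benjamini-Hochberg adjustment called 0 of 7985 genes, and limma voom on recovered reads also called 0. An unadjusted p under 0.05 was found for 177, fewer than chance gives on average. The Turandot genes, which passed in males and not in females, had differences of 0.96 for TotA (SE 1.05), 1.64 for TotC (SE 1.03) and 1.196 for TotM (SE 1.08), all with limma adjusted p = 0.999. Xrp1 differed by −0.09 (SE 0.105), Arc1 by −0.03 (SE 0.318) and CG9377 by 0.32 (SE 0.226). Among genes with a higher change in females the smallest p-values belonged to CG3847 (−0.28, SE 0.081), CG1316 (−0.19, SE 0.054), CG1578 (−0.15, SE 0.043), rictor (−0.19, SE 0.063) and mei-9 (−0.26, SE 0.089). Among those with a higher change in males they belonged to asRNA:CR43885 (0.71, SE 0.213), CG3335 (0.31, SE 0.097), Wwox (0.27, SE 0.088), Alg-2 (0.20, SE 0.068) and asRNA:CR45874 (0.40, SE 0.13), which lies antisense within RpS9. Each had a limma adjusted p of 0.999, and no list passed camera, glycolysis genes coming nearest (adjusted p = 0.0714). Leaving out female control 4 let lncRNA:roX1 pass (0.86, limma adjusted p = 0.0212) and leaving out male PDE 6 let asRNA:CR44095 pass (−1.60, limma adjusted p = 0.0158).

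The female and male changes went together in part across genes. All 5 genes called in both sexes, Arc1, Arc2, CG14695, Xrp1 and CG9377, had the same direction, where independent lists would share 0.00626 genes, and the comparisons have no library in common. Across the 7985 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.513 and Spearman rho = 0.193. In 99 permutations of the treatment labels within each sex r had a median of −0.003 and ran from −0.538 to 0.574. Of these 1 was at or above the real value, a count of positive r alone, since the lowest was larger in size with the opposite sign. Without female control 4 the real r was 0.371.

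**Figure D4:**
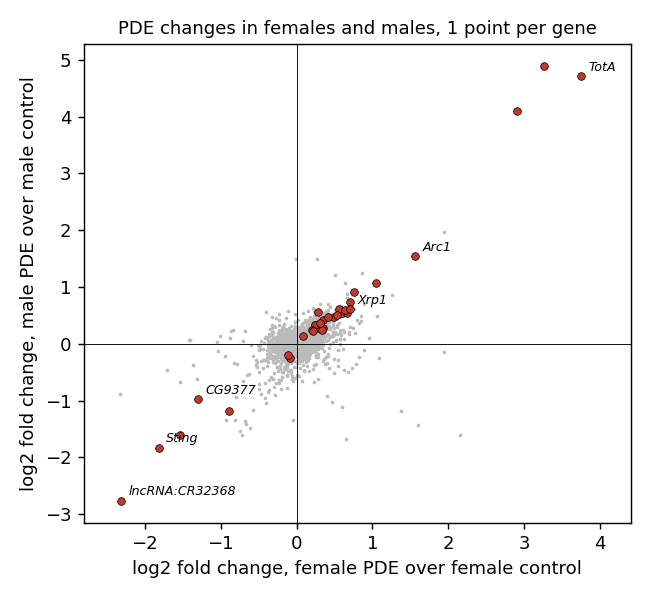
Log2 fold change on the log2(RPKM + 1) scale after PDE in females (horizontal axis) and males (vertical axis), 1 point per gene, with the 33 genes that passed in the average in red. The red points lie in the upper right and lower left quadrants, which the choice of genes by the mean of both changes favours. They reach from near the origin, with sxc at 0.09 and 0.14, to TotA at 3.75 and 4.71 and lncRNA:CR32368 at −2.31 and −2.77.

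Between the sexes, the control brains differed in 379 genes, 126 higher in males and 253 higher in females, and the PDE brains in 393, 132 and 261. roX1 and roX2 were higher in male controls by 6.49 (SE 0.175) and 6.08 (SE 0.168) on the log2 scale (limma adjusted p = 1.27e-18 for both). They were at 2025 ± 106 and 185 ± 40.2 RPKM against 23.4 ± 9.70 and 1.80 ± 0.808 RPKM (SD, n = 7 and 5). Next came Obp99b (2.44, SE 0.487), brv3 (1.73, SE 0.12), CG4586 (1.54, SE 0.091), CG14770 (1.46, SE 0.112), asRNA:CR45479 (1.24, SE 0.082) and nod (1.14, SE 0.114), which lies beside roX2. The yolk protein genes Yp1, Yp2 and Yp3, which are on the fat body list, differed by −4.16 (SE 0.7), −4.07 (SE 0.755) and −3.78 (SE 0.712). They were followed by fit (−3.06, SE 0.819), Obp99a (−2.31, SE 0.551), lncRNA:CR43837 (−1.84, SE 0.319), Cht2 (−1.51, SE 0.204) and asRNA:CR45629 (−1.26, SE 0.105). Yp1 ran from 45.7 to 2570 RPKM in female controls and from 6.85 to 34.7 RPKM in male controls. For Yp2, Yp3, fit, Obp99a and Cht2 the groups overlapped, with female control 1 below the highest male control in each. The yolk protein genes are related in sequence, and nod shares 2219 bases, asRNA:CR45479 1836, asRNA:CR45629 1227 and Yp1 875 with a gene on the opposite strand, so their values can hold reads of those.

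Of the genes of sex determination and dosage compensation, Sxl was lower in male controls (30.5 ± 1.45 against 51.2 ± 6.16 RPKM; −0.72, SE 0.057, limma adjusted p = 3.3e-09). tra was lower too (−0.29, SE 0.064, limma adjusted p = 0.00636), while msl-2 was higher (0.27, SE 0.043, limma adjusted p = 0.000267). mle, mof and fru did not pass (0.05, SE 0.057; 0.18, SE 0.068; 0.10, SE 0.065). After PDE roX1 differed by 7.07 (SE 0.166), roX2 by 6.10 (SE 0.16), Sxl by −0.64 (SE 0.054) and Yp1 by −5.05 (SE 0.665), all passing. Of the 379 and 393 genes 245 were shared, all in the same direction (10.4 for independent lists). X-linked genes made up 74.6% of the genes higher in male controls and 65.2% of those higher in female controls, against 16.5% of the genes tested (Fisher's exact test, p = 5.37e-48 and 2.87e-70). The median log2 difference was −0.05 for X-linked genes and −0.005 for the others.

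Nuclear genes of the respiratory chain ranked higher in males (camera adjusted p = 8.83e-13 in controls and 8.5e-10 after PDE; adjusted p = 0.989 and 0.935 with an estimated correlation). In controls 6 of 67 passed over all genes, among them ND-75 (0.33, SE 0.065), UQCR-C1 (0.32, SE 0.082), UQCR-C2 (0.31, SE 0.082) and blw (0.30, SE 0.084). Adjusted over the list alone 16 were higher and 1 lower, while after PDE 0 passed over all genes or over the list alone. Heat shock proteins and chaperones ranked higher in males (camera adjusted p = 1.09e-05 and 2.83e-06), with Hsp60A (0.35, SE 0.067) and DnaJ-1 (0.40, SE 0.088) passing over all genes in controls and 6 adjusted over the list alone, and 3 and 4 after PDE. TCA cycle genes ranked higher (camera adjusted p = 4.64e-06 and 0.000489), with Ogdh at 0.16 (SE 0.038) the 1 that passed over all genes in controls and 8 adjusted over the list alone, and 0 on both counts after PDE. Mitochondrial ribosomal proteins did (0.0194 and 0.000148 as camera adjusted p), with mRpL16 at 0.50 (SE 0.099) and mRpS25 at 0.41 (SE 0.108) passing on both counts. Glutathione S-transferases did too (camera adjusted p = 0.0303 and 0.0217), of which 0 passed in controls and after PDE GstD9 (0.71, SE 0.187), and in controls glycolysis genes (camera adjusted p = 0.00885), with Pdhb at 0.30 (SE 0.086) passing over all genes and 2 adjusted over the list alone. After PDE muscle and proteasome genes ranked higher in males (camera adjusted p = 0.00331 and 0.046) with 0 members passing. Fat body genes (camera adjusted p = 0.0194 and 0.00347) and insulin signalling genes (0.0332 and 0.0187) ranked lower in males, with REPTOR at −0.31 (SE 0.085) in controls. Of the fat body genes 3 were lower and 1 higher over all genes in controls, and 4 and 1 adjusted over the list alone, and after PDE 3 and 1, and 5 and 1. Neuropeptides did in controls (camera adjusted p = 0.0332), with Nplp1 at −0.18 (SE 0.05), Proc at −0.43 (SE 0.119) and ITP at −0.36 (SE 0.101) passing over all genes and 4 adjusted over the list alone. Retina genes had a median difference of 0.85 in controls, with 23 of 28 positive, and 0.40 after PDE, with 24 of 28, without passing (camera adjusted p = 0.0731 and 0.152), and 3 male controls and 1 female control were among the 5 retina-rich libraries. With the retina score as a covariate, chosen after seeing the data, the calls of glutathione S-transferases in both states, of insulin signalling and neuropeptides in controls and of the proteasome after PDE ended. With an estimated correlation every list named here had adjusted p = 0.989 in controls and 0.935 after PDE.

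The division of these calls depended on the scaling. Median-ratio scaling gave 210 higher and 231 lower in male controls and 187 and 229 after PDE. Quantile normalization gave 186 and 210, and 172 and 217. limma voom on recovered reads, chosen after seeing the data, gave 202 and 258, and 220 and 249. Without the 5 libraries rich in retinal transcripts 176 genes differed between the control groups, and without female control 1 there were 250. In controls the mitochondrial ribosomal proteins no longer ranked apart without female control 3 or male control 1 or 4 (camera adjusted p up to 0.884), glutathione S-transferases without female control 1 or male control 4 or 6 (up to 0.784), glycolysis without female control 1 (0.22) and insulin signalling without female control 1 or 3 or male control 4 (up to 0.291). Neuropeptides did not without female control 5 or male control 4, 6 or 7 (camera adjusted p up to 0.109), nor fat body genes without female control 2 or 3 or male control 1 (up to 0.122). After PDE glutathione S-transferases did not without female PDE 7 or male PDE 3 (camera adjusted p up to 0.183), insulin signalling without female PDE 7 (0.0788), muscle without male PDE 1 (0.0506) and proteasome genes with 7 of the 25 libraries left out in turn (up to 0.277). The call of fit ended with 6 of the 25 libraries left out in turn (limma adjusted p up to 0.109) and that of Obp99a without female control 2 (0.0557).

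Genes detected, the RPKM sum and the share of the 10 highest genes did not differ with PDE beyond the spread between libraries. Library totals were not tested. In males they ran from 27.83 M to 58.73 M reads in controls and from 11.2 M to 28.26 M after PDE. All male controls but male control 1 were deeper than every male PDE library, so depth goes largely with treatment there. Its effect on the male calls was not tested beyond leaving out libraries. Genes detected at 1 RPKM or more numbered 7670 ± 77.4 and 7693 ± 72.0 in female control and PDE libraries (SD, n = 5 and 7; exact two-sided permutation p = 0.619). In males they numbered 7682 ± 92.3 and 7682 ± 74.6 (SD, n = 7 and 6; exact permutation p = 0.987). The 10 highest genes took 6.67 ± 0.833% and 5.89 ± 0.302% of the RPKM sum in females (exact permutation p = 0.029, adjusted p = 0.174 over 6 tests) and 7.27 ± 0.847% and 6.75 ± 0.628% in males (exact permutation p = 0.237). The RPKM sum differed by −1320 in females (exact permutation p = 0.854) and by 523 in males (exact permutation p = 0.912). Mitochondrially encoded transcripts were not analysed here.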

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

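Of the tests weighed here, those on fat body, on retina, on a DNA variant and on depth as the whole source of the retinal spread were chosen only after the results were seen, while those on antimicrobial peptides, on genes regulated by STING and on the correlation with library depth were set before their results were seen.

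In each group of 4 to 10 libraries, the highest or lowest value was set apart where its gap to the nearest other library, as a share of the group's range, passed Dixon's limit. Chance passes it in about 1 in 20 groups. Of 220 combinations of a named gene and a group 13 passed, where 11 are due to chance, and of 16 combinations of a library measure and a group 5 passed, where 0.8 are.

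The library totals gave 4 of these. Female control 3 had 8.88 M reads where the next library had 21.89 M (gap share 0.76), and male PDE 1 had 11.2 M where the next had 23.08 M (0.7). At the other end female PDE 3 had 48.3 M against 31.47 M (0.63) and male control 7 had 58.73 M against 38.15 M (0.67). In male PDE 3, the library of its group with the most retinal transcripts, the 10 highest genes took 8.0% of the RPKM sum against 6.63% (0.79).

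Among the genes called under PDE, Sting stood at 7.17 RPKM in female control 3, against 25 in the nearest female control (0.87). CG17224 stood at 3.09 RPKM in male PDE 6, against 0.86 (0.77). Arc2 was at 2.24 RPKM in male control 5, against 3.04 (0.58), CG9377 at 20.5 RPKM in female control 5, against 13.6 (0.74), and sxc at 22.5 RPKM in female control 3, against 20.5 (0.78). Each of these libraries lay on its group's own side of the other treatment except female control 3, where Sting and sxc were within the range of the PDE libraries, and male PDE 6, where CG17224 was within the control range.

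Among the other genes asRNA:CR43885 was at 17.0 RPKM in female PDE 4, against 23.4 (0.59), asRNA:CR45874 at 6.75 RPKM in male PDE 1, against 4.97 (0.63), and CG1578 at 30.1 RPKM in male control 5, against 28.2 (0.59). The sex-biased nod was at 1.32 RPKM in female control 4, against 0.506 (0.73), and Cht2 at 2.75 RPKM in male control 6, against 1.37 (0.72). asRNA:CR45629 was at 0.0462 RPKM in male control 2 and listed at 0 in the other male controls (1.0). Trxr1 was at 27.1 RPKM in female PDE 6, against 23.7 (0.6), and cry at 35.3 RPKM in male control 4, against 28.4 (0.65).

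The low Sting of female control 3 belongs to a wider pattern: Sting, lncRNA:CR32368, CG17224 and CG17264 fell together under PDE and also varied together within groups (Sting with lncRNA:CR32368 r = 0.93, rho = 0.93, r = 0.9 without the 2 farthest libraries; Sting with CG17224 r = 0.9, rho = 0.91, 0.84 without them; permutation p = 1e-05, the smallest 100000 permutations can give, adjusted p = 1.83e-05 over 11 relations). The median r of Sting, lncRNA:CR32368 and CG17224 was 0.93 and at least 0.91 without any 1 library, which argues against a DNA variant acting on its neighbours alone, since the genes lie on 2R, 3L and 2L. With the retina and fat body scores as covariates Sting changed by −1.9 on the log2 scale (SE 0.34). This argues against more fat body in the control libraries as the source of its fall, although fat body genes did rank lower under PDE. An antiviral state driven by STING that was stronger in the control flies stays open. Its known targets Srg1, Srg3 and Nazo were near the floor. Their correlations with Sting within groups were 0.13, 0.11 and 0.4 (permutation p = 0.502, 0.392 and 0.0939), with a median of 0.13 (± 0.12, taken over these genes). Their averaged log2 changes were −0.21, −0.1 and −0.62, but in males the means of Srg1 and Srg3 were higher after PDE. In male controls 1 and 2 Sting was at 72.5 and 53.6 RPKM and lncRNA:CR32368 at 285 and 252 RPKM. The next highest male control was at 15.8 and 54.4 RPKM. In female controls and after female PDE lncRNA:CR32368 was also highest in replicate 1, but after male PDE it was lowest there. Sting kept its averaged call with the replicate number as a block, and a batch behind these numbers was not tested. An effect of PDE may be considered as a hypothesis, beside a difference in genetic background between flies, which was not tested.

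The rise of TotA, TotC and TotM under PDE was weighed against other tissue. The fat body list, a known source of Turandot proteins, had a median log2 change of −0.23 (± 0.24). This error is taken over member genes as if independent, so it is too small where they vary together (estimated correlation 0.54). With the retina and fat body scores as covariates TotA changed by 4.65 (SE 0.496), which argues against a larger amount of fat body as the source. A change of Turandot expression within the fat body left on the brains would not be seen this way and was not tested. With the retina score as a covariate TotA changed by 4.3 (SE 0.52), against 4.23 without it (SE 0.526), which argues against retina as the source. Haemocyte genes ranked higher under PDE with camera, though not with an estimated correlation, and haemocytes as the source were not tested. A wider secretion of stress and immune peptides stays open, since antimicrobial peptides had a median of 0.16 (± 0.15, likewise over genes) over members on both sides. Induction by PDE may be the source of this rise, as a hypothesis that these libraries cannot separate from a difference between the flies of the groups.

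The spread of retinal transcripts between libraries of 1 group was weighed against preparation and depth. Within groups the retina genes varied together with a median pairwise r of 0.69, and the retina score followed that of the eye pigment cells (r = 0.92, rho = 0.91, permutation p = 1e-05, adjusted p = 1.83e-05, r = 0.89 without the 2 farthest libraries). These are the values that unequal amounts of retina left on the brains would give, and this is a candidate explanation. Without the 2 shallowest libraries and the trend with depth the SD of the retina score within groups was 1.18 (SE 0.2), against 1.15 over all 25 libraries, which argues against depth as the whole source, while a smaller part that goes with depth stays open (r = 0.21, ± 0.22, rho = 0.16, permutation p = 0.358, adjusted p = 0.431, r = 0.28 without the 2 farthest). No biological explanation was tested. The retina-rich libraries were female control 4, male controls 4, 5 and 6 and male PDE 3. As most of these were controls, an effect of PDE on retinal transcripts cannot be told apart from preparation here.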

How the results depend on the processing

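The tests with recovered reads, with covariates, without the 2 shallowest libraries and without the 5 retina-rich libraries were chosen only after the results were seen, and the others were planned. Depth limits female control 3 and male PDE 1 most, with 8.88 M and 11.2 M reads.

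The named genes gave 49 calls, each of 1 gene in 1 comparison, of which 27 kept call and direction under all alternatives run, 22 lost the call under at least 1, and 0 changed direction. Xrp1, Arc1 and CG9377 kept it in both sexes, CG14695 and TotA in males (TotA with limma adjusted p up to 0.0411), Gadd45, GstE1, Sting and CG17224 in the average (Sting up to 0.0167), and roX1, roX2, Yp1, Yp2, Yp3, Sxl and msl-2 between the sexes. TotC lost its male call with limma voom on recovered reads (adjusted p = 0.606, range 0.000115 to 0.606 over the alternatives), as did TotM (0.657, range 0.00238 to 0.657), which also lost it with pseudocount 5 (0.107) and without the retina-rich libraries (0.276). Of 51 calls of 1 list in 1 comparison 17 kept call and direction, 33 lost the call somewhere and 8 changed direction. Of 52 results of a named gene without a call 17 changed direction and 1 passed somewhere, and of 153 results of a list without a call 69 passed somewhere. Counts in the average ran from 22 to 45. Robust moderation was not run for lists, and a fit of only the groups compared has no average or difference of the sexes. No scaling moved the median of all genes by over 0.1.

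With only the groups compared 3 genes passed in females and 176 between the sexes in controls, where the spread was estimated from fewer libraries. With array weights 25 passed in males and 664 between the sexes after PDE. Without the retina-rich libraries 6 passed in males and 176 between the sexes in controls, with fewer libraries. With each library left out in turn, male counts ran from 8 (without male control 2 or 5 or male PDE 3, 4 or 5) to 17 (without female control 3), with 9 without male control 1, 3 or 4 or male PDE 1 or 6. The limma count for the difference of the changes ran from 0 to 1 (without female control 4 or male PDE 6), was 0 with limma voom, and was 177 at an unadjusted p under 0.05. The count between the sexes in controls ran from 250 (without female control 1) to 449 (without female control 4). The correlation of the female and male changes ran from 0.371 (without female control 4) to 0.576 (without male control 6). For array weights and single libraries the cause was not tested.

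The genes below were uncalled, and the cause of their changes of sign was not tested. With array weights the log2 changes in females were −0.066 for Sod1, −0.033 for Sod2, −0.179 for GstD1, −0.005 for Trxr1, −0.025 for Hsp68 and −0.018 for cry. In males they were 0.019 for Gclc and 0.118 for Thor, and in the average −0.001 for Sod1, −0.04 for Sod2, −0.028 for GstD1 and 0.125 for Thor. Without the 2 shallowest libraries they were −0.037 for Sod1, −0.006 for GstD1 and −0.192 for Thor in females, 0.018 for Gclc in males and −0.016 for Sod2 in the average. limma voom on recovered reads gave −0.177 for Thor in females and quantile normalization 0.128 for ninaE. With the retina covariate they were 0.257 for ninaE in females, 0.019 for Thor in males and 0.035 for Thor in the average. With both covariates they were −0.017 for Thor and 0.372 for ninaE in females, 0.017 for Sod2 in males and 0.022 for ninaE in the average. Without the retina-rich libraries they were 1.188 for ninaE in females, 0.008 for Gclc and 0.185 for Thor in males, and 0.158 for Thor and 0.349 for ninaE in the average.

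With each library left out in turn, the female changes ran from −0.037 to 0.155 for Sod1, from −0.142 to 0.211 for GstD1, from −0.194 to 0.352 for Thor and from −0.884 to 1.188 for ninaE. The male changes ran from −0.034 to 0.018 for Gclc, from −0.187 to 0.134 for Thor and from −0.03 to 0.08 for cry. The averaged changes ran from −0.021 to 0.096 for Sod2, from −0.029 to 0.148 for GstD1 and from −0.123 to 0.15 for Thor. PDE minus control differences of genes detected ran from −7.54 to 39.7 in females and from −19.5 to 27.5 in males, and those of the RPKM sum from −8080 to 2560 and from −1580 to 3560.

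Lists that changed direction are given with their camera adjusted p, and the cause was not tested. Glycolysis in females had 0.968 with array weights (lowest over the alternatives 2.68e-07). Retina genes had 0.565, 0.791 and 0.7 in females, males and the average without the retina-rich libraries (lowest 0.000226, 6.48e-08 and 8.41e-07), and in females ran from 0.000226 to 0.89 (without female control 4) with each library left out. Respiratory chain genes in males had 0.947 with both covariates (lowest 0.000323), and fat body genes between the sexes after PDE had 0.963 (lowest 0.000637), where the covariate is the list itself. Pan-neuronal genes in the average had 0.741 without the 2 shallowest libraries (0.001 to 0.83 over all alternatives) and ran from 0.001 to 0.447 (without female control 3) with each library left out. Mitochondrial ribosomal proteins between the sexes in controls had 0.892 without the 2 shallowest libraries (lowest 1.44e-05) and ran from 0.000443 to 0.884 (without female control 3).

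The labels number the replicates of each group, and 16 of 34 pairs of samples with the same number had deviations that correlated above 0.1 (range −0.688 to 0.75, median 0.081), against 64 of 199 other pairs (median −0.026). As not every pair did, the numbers were not taken to pair the samples. A weaker structure that goes with the number is not excluded by this, so the replicate block was run beside the main fit. With the replicate block limma called 6 genes in females (5 shared with the fit without it), 13 in males (13 shared), 35 in the average (29 shared), 0 for the difference of the changes, and 347 and 418 between the sexes, and r was 0.471. Under the block Thor was at −0.137 and ninaE at 0.258 in females, and Gclc at 0.009 and Thor at 0.031 in males.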

Other observations

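The set of genes that follow Sting and a measure that parts the libraries of the largest split were looked for, and the genes outside the rule here were chosen, only after results were seen, while the splits of the libraries were planned.

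A few single genes of the DNA repair list differed between the sexes. XRCC1, a scaffold of single-strand break repair, was higher in males by 0.68 on the log2 scale in controls (SE 0.1, limma adjusted p = 9.03e-05) and by 0.61 after PDE (SE 0.095, limma adjusted p = 0.000136). Xpac of nucleotide excision repair was higher by 0.35 (SE 0.08, limma adjusted p = 0.00876) and 0.42 (SE 0.076, limma adjusted p = 0.000854), and Ercc1 passed after PDE (0.33, SE 0.082, limma adjusted p = 0.0175). mei-9 was lower in males after PDE (−0.26, SE 0.061, limma adjusted p = 0.0102). Of the 24 measured genes of the DNA repair list 2 were higher and 0 lower in male controls, over all genes and adjusted over the list alone. After PDE 3 were higher and 1 lower over all genes, and 3 higher and 2 lower adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.968 and 0.674).

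Among signalling genes the JAK-STAT receptor gene dome was higher in males in controls (0.27, SE 0.054, limma adjusted p = 0.00262) and after PDE (0.18, SE 0.051, limma adjusted p = 0.0355). dl of the Toll pathway was lower in males in both states (−0.47, SE 0.102, and −0.37, SE 0.096; limma adjusted p = 0.00598 and 0.0252), while the caspase gene Dredd was higher in male controls (0.55, SE 0.104, limma adjusted p = 0.00177). The clock gene tim was lower in male controls (−0.35, SE 0.087, limma adjusted p = 0.0191) and the neuropeptide receptor gene Pdfr in males after PDE (−0.21, SE 0.059, limma adjusted p = 0.0327). After PDE the stress genes Hsp68 (0.36, SE 0.106, limma adjusted p = 0.0477) and Hsp70Bb (0.37, SE 0.107, limma adjusted p = 0.0445), the latter 1 of several near-identical copies, were higher in males than in females.

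Among the other 7984 genes 4 had a correlation with Sting above 0.8 within groups and 0 one below −0.8. Besides lncRNA:CR32368, CG17264 and CG17224 this was Charon, a regulator of immune transcription, with an averaged change of −0.58 that did not pass (SE 0.14, limma adjusted p = 0.0859). All 4 were lower under PDE.

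As a check on chance, the libraries were divided in 100 ways into groups of the same sizes, the real one included. For the female comparison 4 of the 100 gave as many as the 6 genes found, the highest other giving 1155, which points to a structure of the samples. That split set female control 3 and female PDE 1, 3, 5 and 7 against the other female libraries, with RPKM sums of 178087 to 201959 against 202446 to 220635. The cause of this difference was not tested, and the RPKM sum did not differ with PDE in females beyond the spread between libraries (exact permutation p = 0.854). For males 1 of 100 did (14 genes, highest other 1) and for the average 1 (33, highest other 4). For the sexes it was 1 in controls (379, highest other 16) and 1 after PDE (393, highest other 188). For males, the average and the sexes only the real division gave as many genes, which is under 5 in 100. For females 4 in 100 lies too near that limit for 100 splits to decide, so chance is not excluded there. For the difference of the changes the splits decide nothing, because limma found 0 genes (177 at an unadjusted p under 0.05, and 0 with limma voom) and so all 100 gave as many, the highest other giving 9.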
